A study of Mus musculus with 6 samples.

How the data were processed

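RNA from mouse fetal livers at embryonic day 14.5 was compared between 3 wild-type libraries and 3 libraries of a Gata1 3′ UTR knockout. Total RNA was isolated with TRIzol and sequenced as paired ends of 150 bases, per the labels' protocols. The authors deposited 1 table of FPKM per gene and library with annotation text. The aligner, the counting program, the genome build and the use of strand are not given in the sources used here. Of 26014 gene identifiers 25935 (99.7%) occur in GENCODE M21, and 23607 rows have the same positions as there, so coordinates are given as GRCm38.

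Of 26022 lines after the header, 7 held annotation text that had spilled from the line before and 1 was empty, and these were left out. Gene names that a spreadsheet had turned into dates (24) were restored from the identifiers, and of rows that share a symbol the one with the highest mean kept it. Low FPKM values step by the worth of 1 fragment. With merged exon lengths from the annotation, 92.4% to 92.9% of the values checked in each library (11049 to 11540 values) came out as whole fragments within 0.02, at about 14800000 to 16200000 fragments per library. A gene with 1 kb of exons and 3 fragments then has 0.185 to 0.202 FPKM, which limits what can be read of low genes. This covers counting error only.

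The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2 of FPKM + 1, two-sided, over the 11142 genes with a mean FPKM of at least 1 in the 6 libraries, without a replicate block. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. With 3 against 3 libraries an exact permutation test of a single gene cannot go below p = 0.1, so the test borrows the spread from all genes (prior degrees of freedom 2.86, residual 4). Gene lists, 34 in all and fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where they had at least 3 tested members (31 lists), and 3 were described gene by gene. Each list was also tested with an estimated correlation and with fry. With an estimated correlation many lists shared adjusted p = 0.64, since the adjustment can give unlike p-values the same result. Unadjusted p of these lists (camera) ran from 0.093 for genes activated by GATA1 to 0.31 for S phase and DNA replication. It was 0.26 for megakaryocyte and platelet markers. Gene Ontology terms from the deposited annotation with 10 to 300 tested members were tested with camera against all tested genes.

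The genes named in the text followed a rule fixed before the data were examined: Gata1, the 10 largest positive and 10 largest negative log2 fold changes among changed genes whose libraries did not overlap, up to 4 members of each list with the smallest p, and all members of the lists described gene by gene. Other members of a list are named where a count is spelled out, and these, like Alb, Ppbp and Rn7sk, were chosen after their values were seen. Some genes that the rule takes are not reported here.

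On simulated fragments for 11037 genes, with 50 genes changed at each size, the test recovered 2% of changes of 1.25-fold, 48% of 1.5-fold and 98% each of 2-fold and 4-fold, and 3 of 126 calls were false. The simulation drew genes independently with a common spread and had no effects shared by the genes of a library. Its rates therefore need not hold for these data, where markers of a cell type moved together. Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios, TPM and non-globin scaling, a replicate block, library weights, a robust prior, a minimum absolute log2 fold change of 1, each library left out, protein-coding genes alone and limma's voom on the recovered fragments. The last 2 were added after the data were examined. TPM and non-globin values were not brought back to the size of the FPKM values. The same filter and pseudocount therefore weighed less, and 13376 and 14186 genes were tested. Calls lost with these scalings can reflect this as well as the scaling. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the table and drew the figures.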

Results

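The series profiled RNA of mouse fetal livers at embryonic day 14.5, when this organ is the main site of red cell production. There were 3 libraries from wild-type embryos (WT) and 3 from embryos described as a knockout of the Gata1 3′ UTR (KO), the part of the messenger RNA after the stop codon. The labels call the cells embryonic hepatocytes and give no sort. The stated purpose was to find genes and pathways that differ during fetal erythropoiesis. The deposited values are FPKM, fragments per kilobase of exon scaled to the fragments of the library, for 26014 genes. Steps in the low values place the depth at about 14800000 to 16200000 fragments per library, and 20235 to 21290 genes were above 0 in each. The labels do not say that the libraries came from separate embryos, so p-values measure the spread between these samples, which may be technical.

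Gata1, the erythroid and megakaryocytic transcription factor whose UTR was targeted, fell in KO to 45.1% of its WT level. Its level was 150.1 ± 13.6 FPKM in WT and 67.7 ± 0.486 FPKM in KO (SD, n = 3 each). The log2 fold change was -1.13 with a standard error of 0.069, and all KO libraries lay below all WT libraries (limma, adjusted p = 0.000638). The gene, ENSMUSG00000031162, lies on the minus strand of chromosome X from 7959260 to 7978071, positions that equal those of GRCm38. In the transcript Gata1-201 the 3′ UTR covers 7959260 to 7959756, which is 497 of 1902 bases. FPKM counts fragments over all exons, the 3′ UTR included, so fragments missing from a deleted part also lower the value. The extent of the deletion is not given in the sources used here. The 3′ UTR makes up 26.1% of Gata1-201 and 20.4% of the merged exons. With even coverage, losing all of it would leave 73.9% of the transcript, above the 45.1% of the WT level seen. This argues against missing UTR fragments as the whole cause, although coverage along the gene could not be seen. Of the related factors, Gata2 had 5.92 ± 1.72 FPKM in WT and 9.56 ± 1.16 in KO and did not pass the test (limma, adjusted p = 0.066), nor did Gata4. Of 12 tested neighbours of Gata1 on the chromosome, 1 passed, Was, an actin regulator of blood cells, with a log2 fold change of 0.47, a call kept in 1 of the 6 fits that each left out 1 library and lost with no filter and with median-of-ratios scaling (adjusted p up to 0.1311). None of the 4 tested Y-linked genes passed, and all were above 0 in every library.

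**Figure D1:**
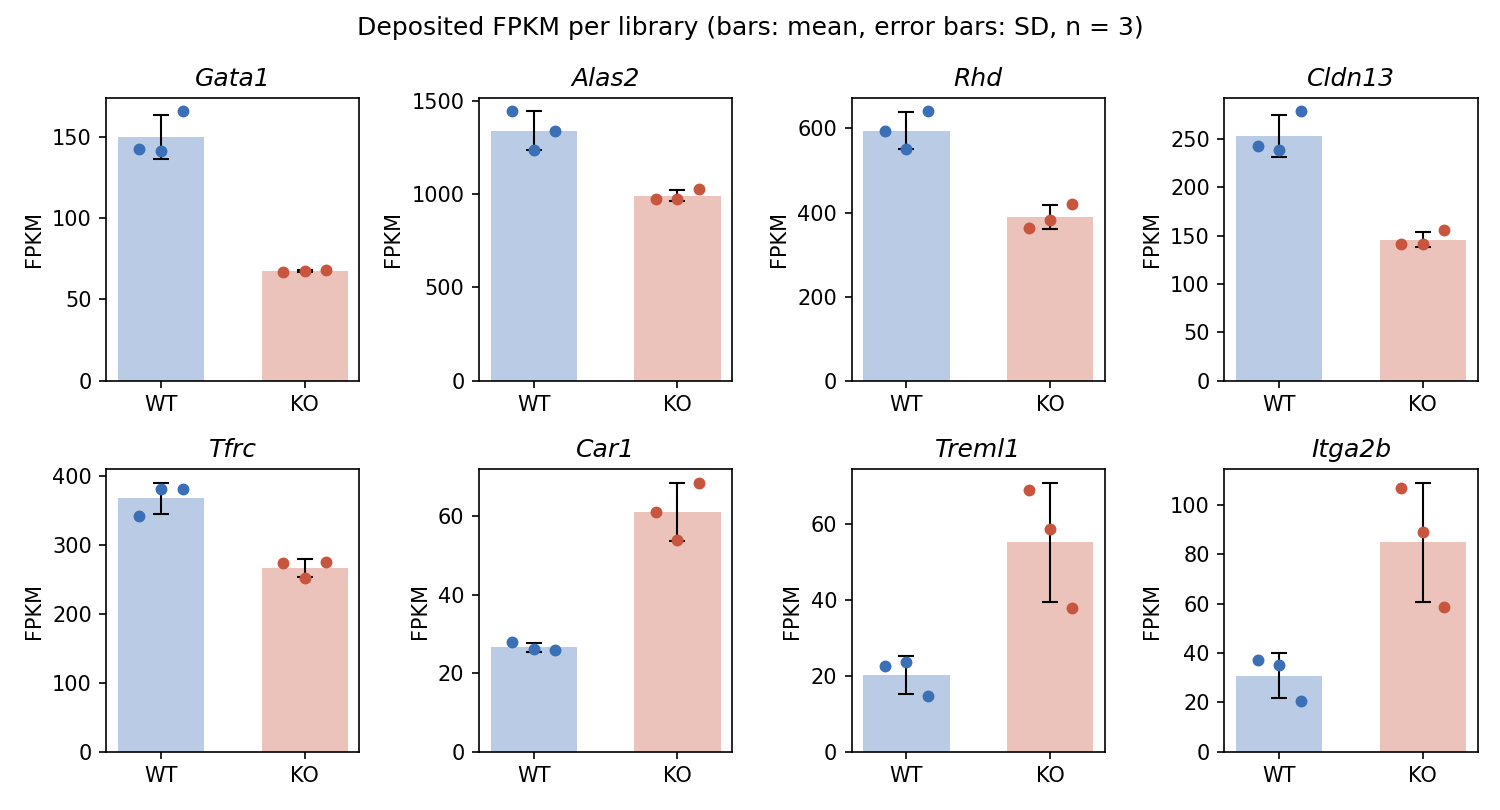
FPKM (vertical axes, from 0) of 8 genes in WT and KO libraries, with points for libraries, bars for means and error bars for SD (n = 3). Gata1 stood at 150.1 FPKM in WT and 67.7 in KO, and the points of the groups do not overlap in any panel. All 8 genes shown were past the threshold, which makes this likely.

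Across the transcriptome 661 genes rose and 403 fell in KO among 11142 tested (limma on log2 of FPKM + 1, adjusted p under 0.05). Rises of at least 2-fold numbered 58 and falls of that size 42. Of all tested genes 7952 had a positive log2 fold change and 3190 a negative one. All 1064 changed genes had libraries that did not overlap between the groups, which the selection by the test makes likely. The same held for 35.6% of tested genes against 10% by chance for a gene without a group difference. A shift shared by many genes can also raise this share. The split between higher and lower genes changed with the scaling of the libraries, which with TPM also let more genes past the filter (13376). With median-of-ratios scaling 251 genes were higher and 495 lower, and with TPM scaling 627 were higher and 137 lower, while the median log2 fold change of all tested genes was 0.09 as deposited, 0.01 with median-of-ratios and 0.21 with TPM. The TPM factor was 1.163 in WT replicate 1 and 0.948 to 0.998 in the other libraries, so that library stands apart in this alternative. Counts fell to 62 higher and 111 lower without KO replicate 2, to 97 and 127 without KO replicate 1, to 220 and 202 without WT replicate 3, to 271 and 224 without KO replicate 3, and to 439 and 325 without WT replicate 1.

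The largest falls were in Apol11b, Sh3tc2, Btnl10, the transcript 1810053B23Rik, Cd82, Mir7001, Shb, Gm11084, Cd36 and Mcub. Apol11b, at 77633951 to 77643286 on chromosome 15, fell to 0.205 ± 0.0932 FPKM in KO, 2.28% of its WT level, a log2 fold change of -3.05 with a standard error of 0.089 (limma, adjusted p = 6.19e-05). Cd82, a tetraspanin of the cell surface, went from 101.8 ± 7.59 to 21.8 ± 1.57 FPKM. Cd36, a fatty acid and thrombospondin receptor, had a log2 fold change of -1.83, and Mcub, a subunit of the mitochondrial calcium uniporter, of -1.80. Mir7001 lies inside Cd82 on the same strand, so their fragments cannot be separated here, and Gm11084 lies partly inside Sp3. Mir7001 rested on 2 to 7 fragments per WT library and 0 to 1 per KO library, and Gm11084 on 3 to 7 and 0 to 2. With a library left out each kept its call in 1 of 6 fits, and over all alternatives in 9 of 15 and 4 of 16. The largest rises were in Hspa12b, Gm16111, Nrbp2, Fndc5, Cyp2w1, Gm22615, Mir339, Homer2, Gcsam and Gm27529. Hspa12b, a member of the HSP70 family at 131127280 to 131146321 on chromosome 2, went from 3.30 ± 0.236 to 17.9 ± 0.804 FPKM, a log2 fold change of 2.14 (limma, adjusted p = 6.19e-05). Fndc5, which encodes the precursor of irisin, had a log2 fold change of 1.73, and Homer2, a scaffold protein, of 1.55. Gm22615 was listed at 0 in all WT libraries and rested on 1 to 4 fragments per KO library. Mir339 and Gm27529 rested on at most 5 and 12 fragments per library. With a library left out, calls of Gcsam and Gm27529 were kept in 2 of 6 fits, those of Mir339 and Gm16111 in 4 of 6, and that of Gm22615 in 2 of the 4 fits where it was tested. Calls of Gcsam, Gm27529, Gm22615 and Mir7001 were also lost with no filter, that of Gm27529 with non-globin scaling and that of Gm16111 with a pseudocount of 0.1. Gm22615 lies within Zfp934 and Mir339 within 3110082I17Rik, and Hspa12b overlaps Gm11037, each on the same strand. Gm16111 lies within Reln and Gm27529 within Wdr70 on the other strand, and whether the authors' counting used strand is not given in the sources used here.

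Of 24 tested genes of the red cell membrane and cytoskeleton 12 fell, 1 rose and 11 did not pass, and adjusted over the list alone 14 fell and 2 rose. Rhd, a blood group antigen gene, went from 595.2 ± 44.6 to 388.4 ± 28.5 FPKM, with a log2 fold change of -0.61. Cldn13 had a log2 fold change of -0.79 and Aqp1, a water channel, of -0.71, while Cd59a, an inhibitor of complement, rose by 0.33. The list was lower by camera with a preset correlation (adjusted p = 1.445e-11), but adjusted p = 0.64 with an estimated correlation. Of 16 haem synthesis genes 3 fell, and 4 adjusted over the list alone: Alas2, the first and rate-limiting enzyme in red cells, from 1342 ± 103 to 992.3 ± 29.2 FPKM, Fech with a log2 fold change of -0.33 and Slc25a37, a mitochondrial iron importer, of -0.29. In the 6 fits that left out a library, the call of Rhd was kept in 5, those of Aqp1 and Alas2 in 4, and those of Fech and Slc25a37 in 1. All 5 calls were lost with non-globin scaling, all but that of Rhd with TPM scaling, and the 3 haem calls with no filter. In the alternatives adjusted p reached 0.1375 for Alas2, 0.2907 for Fech, 0.3528 for Slc25a37, 0.0785 for Aqp1 and 0.06678 for Rhd. The haem list was lower by camera (adjusted p = 6.429e-06), with adjusted p = 0.64 with an estimated correlation.

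Among 9 globin genes 2 fell, 3 adjusted over the list alone, where 1 also rose. Hbb-bs, an adult beta chain, had a log2 fold change of -0.47 and Hbb-bh1, an embryonic chain, of -0.35, while Hba-x, the embryonic zeta chain, had 1.05 and did not pass (limma, adjusted p = 0.0789). The call of Hbb-bs was lost in all 6 fits that left out a library, with each other scaling and with no filter (adjusted p up to 0.7933, kept in 6 of 17 alternatives), and that of Hbb-bh1 was kept in 1 of those 6 fits and lost with no filter, TPM or non-globin scaling and library weights (adjusted p up to 0.2668). Globin chains nearly identical in sequence can share fragments, which makes their single values uncertain. Camera gave adjusted p = 0.004634 for the lower level of the list, and adjusted p = 0.64 with an estimated correlation. The camera call was lost without WT replicate 1 (adjusted p = 0.0577) and with no filter (adjusted p = 0.1446, range over the alternatives 0.0005977 to 0.1446). Globins took 26.6% to 29.6% of summed FPKM in WT and 22.5% to 24.9% in KO. Of 14 iron uptake and storage genes 1 rose, Ftl1, the ferritin light chain, and 1 fell, Tfrc, the transferrin receptor, from 367.9 ± 22.8 to 267.2 ± 13.2 FPKM. The call of Ftl1 was lost in all 6 fits that left out a library with each other scaling and with no filter (adjusted p up to 0.2642). That of Tfrc was kept in 4 of those fits and lost with TPM and non-globin scaling (adjusted p up to 0.181). Adjusted over the list alone 2 rose and 1 fell, and the list did not pass (camera, adjusted p = 0.6421).

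Of 26 textbook genes activated by GATA1 10 fell, 1 rose and 15 did not pass, with 12 and 3 adjusted over the list alone. Lmo2, a partner of GATA1 in its complex, had a log2 fold change of -0.45 and Trim58, a ubiquitin ligase of late erythroblasts, of -0.65, and the gene that rose was Cdkn1a, an inhibitor of the cell cycle, at 0.40. Of 17 genes repressed by GATA1 4 rose and 13 did not pass, with 9 higher adjusted over the list alone, and all 17 had positive log2 fold changes. Lyl1, a haematopoietic transcription factor, went from 104.2 ± 8.67 to 153.2 ± 2.57 FPKM, Rgs18 had a log2 fold change of 0.92 and Fli1, a megakaryocytic transcription factor, of 0.56. With a library left out, the call of Trim58 was kept in 4 of 6 fits, and those of Cdkn1a, Rgs18 and Fli1 in 1. Those 3 were also lost with no filter and with median-of-ratios and non-globin scaling (adjusted p up to 0.1355, 0.1262 and 0.1629 in the alternatives), and that of Rgs18 with a robust prior. The call of Lmo2 was lost with TPM and non-globin scaling (adjusted p up to 0.1192). The lists were lower (camera, adjusted p = 2.375e-11) and higher (adjusted p = 0.01112), with adjusted p = 0.64 and 0.66 with an estimated correlation. The call of the repressed list was lost without WT replicate 3 (adjusted p = 0.1042, range over the alternatives 7.699e-05 to 0.1042) and without WT replicate 2 (adjusted p = 0.084).

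Of 23 erythroid transcription factors and cofactors 7 fell and 3 rose, and adjusted over the list alone 7 fell and 6 rose. Those lower were Gata1, Lmo2, Klf3, E2f2, Klf13, Klf1 and Sox6, and those higher Tcf3, Stat5a and Stat5b. Klf1, the master regulator of adult globin genes, had a log2 fold change of -0.35. Of 23 genes of late erythroblast maturation, mitophagy and enucleation 6 fell and 3 rose, 7 and 5 adjusted over the list alone. Isg20 went from 22.3 ± 4.35 to 7.18 ± 1.51 FPKM, with a log2 fold change of -1.51, and Ube2l6 and Xpo7 had -0.42 and -0.45. Calls of Ube2l6, Xpo7, Klf3 and E2f2 were kept in 4, 3, 3 and 2 of the 6 fits that left out a library. All 4 were lost with TPM and non-globin scaling, and those of Xpo7 and E2f2 with no filter (adjusted p up to 0.1463, 0.102, 0.2736 and 0.1356 in the alternatives). Camera called both lists lower (adjusted p = 0.00783 and 0.0009293), with adjusted p = 0.64 for each with an estimated correlation. Their medians of -0.04 and -0.11 became 0.08 and 0.05 with TPM scaling. Of 19 early erythroid progenitor genes 4 fell and 1 rose, 5 and 6 adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.2122). Its median was positive, 0.17, while the camera direction was down. The gene that rose, Car1, a carbonic anhydrase of red cell precursors, went from 26.7 ± 1.11 to 61.2 ± 7.33 FPKM, a log2 fold change of 1.16 (limma, adjusted p = 0.0016).

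Megakaryocyte and platelet markers were the list with the largest shift. All 21 tested members had positive log2 fold changes, 14 rose, 19 adjusted over the list alone, and the median log2 fold change was 1.18. The mean level of the list ranged over 0.783 log2 units among WT libraries and 0.806 among KO libraries. WT replicate 3 was lowest of the 6 libraries in this list, at -1.01 from its mean, and also in hepatoblast and hepatocyte (-1.21), endothelial (-0.62) and stellate (-0.53) markers. The same held for stem and progenitor cell markers (-0.44) and genes repressed by GATA1 (-0.34). That library was highest in the red cell membrane (0.21), haem synthesis (0.18), GATA1-activated (0.16), S phase (0.19) and G2 and M phase (0.22) lists. In globin chains and late maturation genes WT replicate 1 was highest (0.27 and 0.15). Itga2b, the platelet integrin alpha IIb, went from 30.9 ± 9.05 to 84.7 ± 24.2 FPKM, and Treml1 and Gp9 had log2 fold changes of 1.38 and 0.90. Of the listed markers 2, among them Fli1, also stand in another list. The list was higher by camera (adjusted p = 7.072e-07), with adjusted p = 0.64 with an estimated correlation. Ppbp, chosen after its values were seen, had 51.0 to 113.9 FPKM in WT libraries and 57.4 to 102.0 in KO. Calls of Itga2b and Treml1 were lost without WT replicate 3, KO replicate 1 or KO replicate 2, with adjusted p up to 0.1107 and 0.09731 in these fits, and also with no filter. Of 14 stem and progenitor cell markers 2 rose, among them Lyl1, 7 adjusted over the list alone, and camera gave adjusted p = 0.03357, with adjusted p = 0.70 with an estimated correlation. That call was lost without WT replicate 2 (adjusted p = 0.1303) and without WT replicate 3 (adjusted p = 0.1688, range over the alternatives 0.001383 to 0.1688), and with a mean FPKM of at least 5 or voom (adjusted p = 0.09019 and 0.05069).

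**Figure D2:**
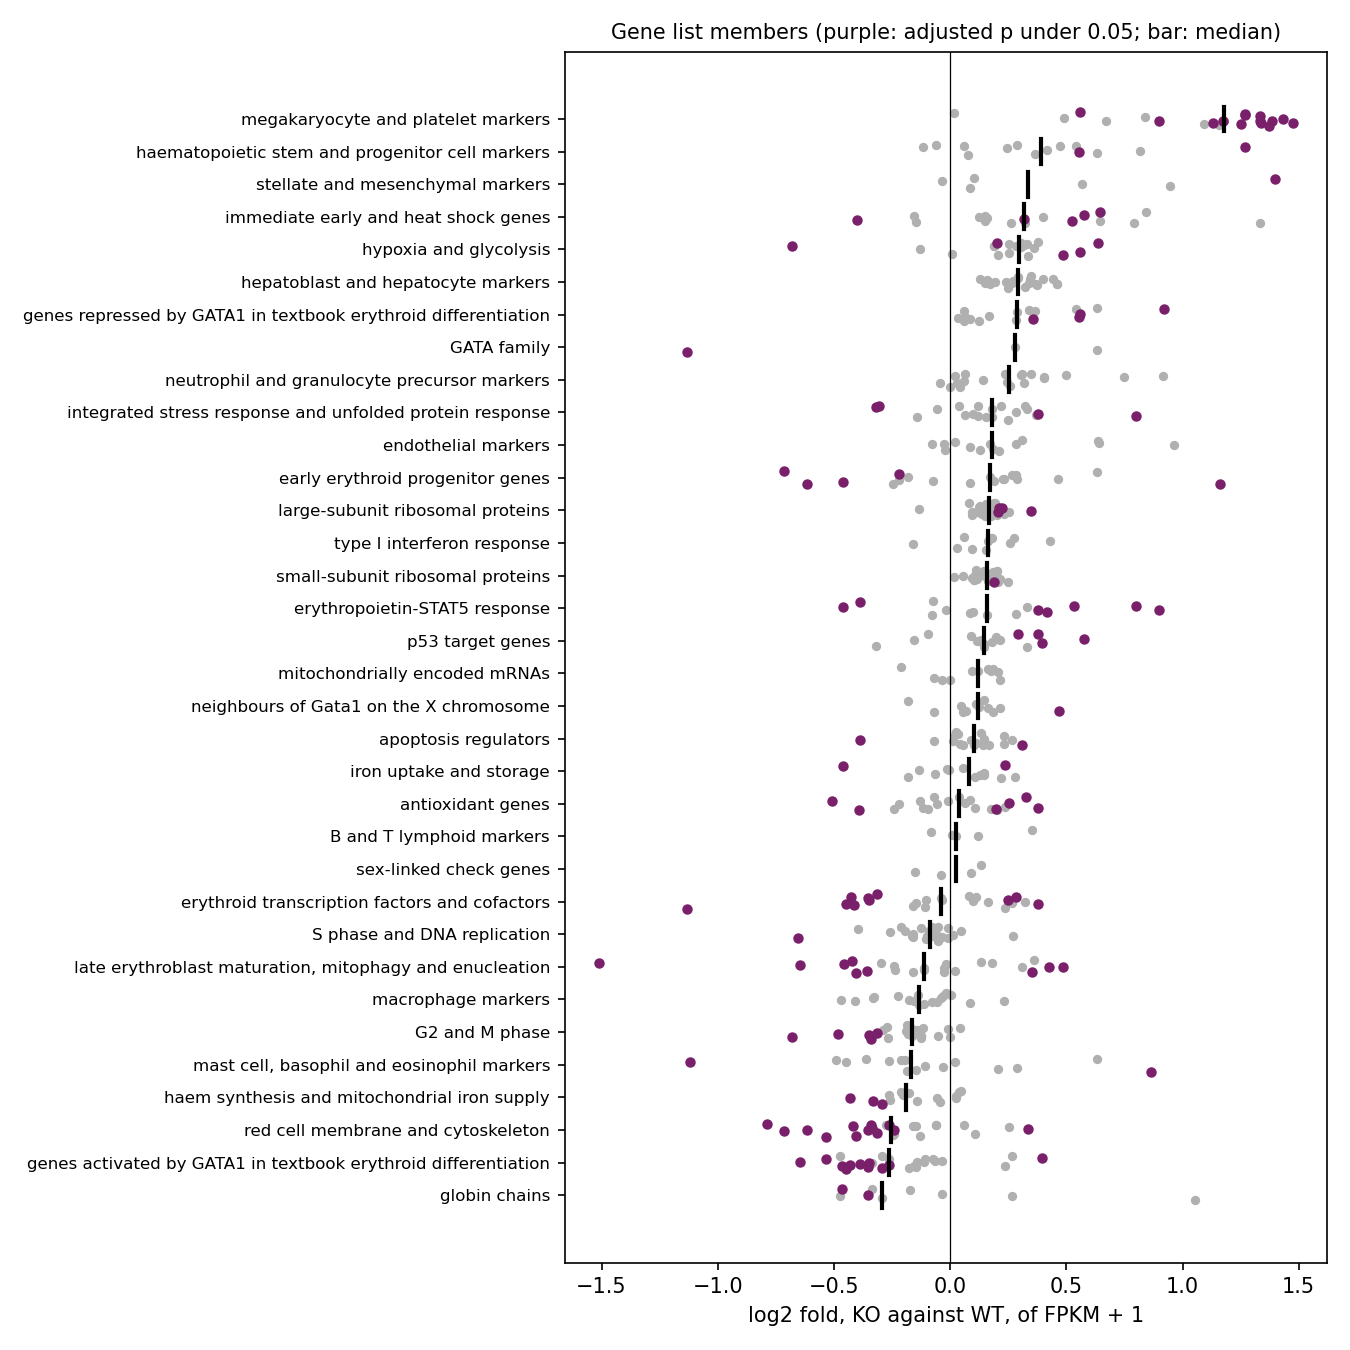
Log2 fold change of FPKM + 1, KO against WT (horizontal axis), of each tested member of 34 gene lists (rows), with purple points for genes past the adjusted threshold and a black bar for the median. Megakaryocyte and platelet markers had the highest median, 1.18, and globin chains the lowest, -0.29.

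Markers of other cells that a fetal liver holds varied between libraries. None of 25 hepatoblast and hepatocyte markers passed, and none adjusted over the list alone, although all 25 log2 fold changes were positive and the camera direction was down (adjusted p = 0.7462). Without WT replicate 2 camera called the list higher (adjusted p = 0.0009209) and without WT replicate 3 lower (adjusted p = 0.001731). Alb, the albumin gene, stood at 353.7, 963.8 and 148.6 FPKM in the WT libraries and at 482.4, 523.1 and 392.9 in the KO libraries, so these cells' RNA differed more among WT libraries than between the groups. None of 19 macrophage, 20 neutrophil, 14 endothelial and 5 lymphoid markers passed. The macrophage list was lower by camera (adjusted p = 0.00909, and adjusted p = 0.70 with an estimated correlation), a call lost without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 3 (adjusted p = 0.06807, 0.1303, 0.1609 and 0.06887, range over the alternatives 1.116e-06 to 0.1609), and with a mean FPKM of at least 5 or median-of-ratios scaling (adjusted p = 0.07428 and 0.0652). The neutrophil, endothelial and lymphoid lists did not pass (camera, adjusted p = 0.3068, 0.7224 and 0.8549), but the neutrophil list was higher without WT replicate 1 (adjusted p = 0.01498) or KO replicate 3 (adjusted p = 0.02252), and with TPM or non-globin scaling (adjusted p = 0.03932 and 0.02749). Of 6 stellate and mesenchymal markers 1 rose, Reln, with a log2 fold change of 1.40 and a call lost without KO replicate 2 (list camera adjusted p = 0.3742, and 0.04303 with non-globin scaling). Of 16 mast cell, basophil and eosinophil markers Il1rl1 rose by 0.87 and Mcpt8 had -1.12 (a call lost without KO replicate 1), with 2 higher and 1 lower adjusted over the list alone. This list was lower by camera (adjusted p = 0.03357, and adjusted p = 0.70 with an estimated correlation), but not without WT replicate 1, KO replicate 2 or KO replicate 3 (adjusted p = 0.541, 0.06853 and 0.1214, range over the alternatives 0.0009209 to 0.541). It was also not called with no filter, a mean FPKM of at least 5, median-of-ratios scaling or voom (adjusted p = 0.1237, 0.3096, 0.1813 and 0.2132), and passed in 10 of 17 alternatives.

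**Figure D3:**
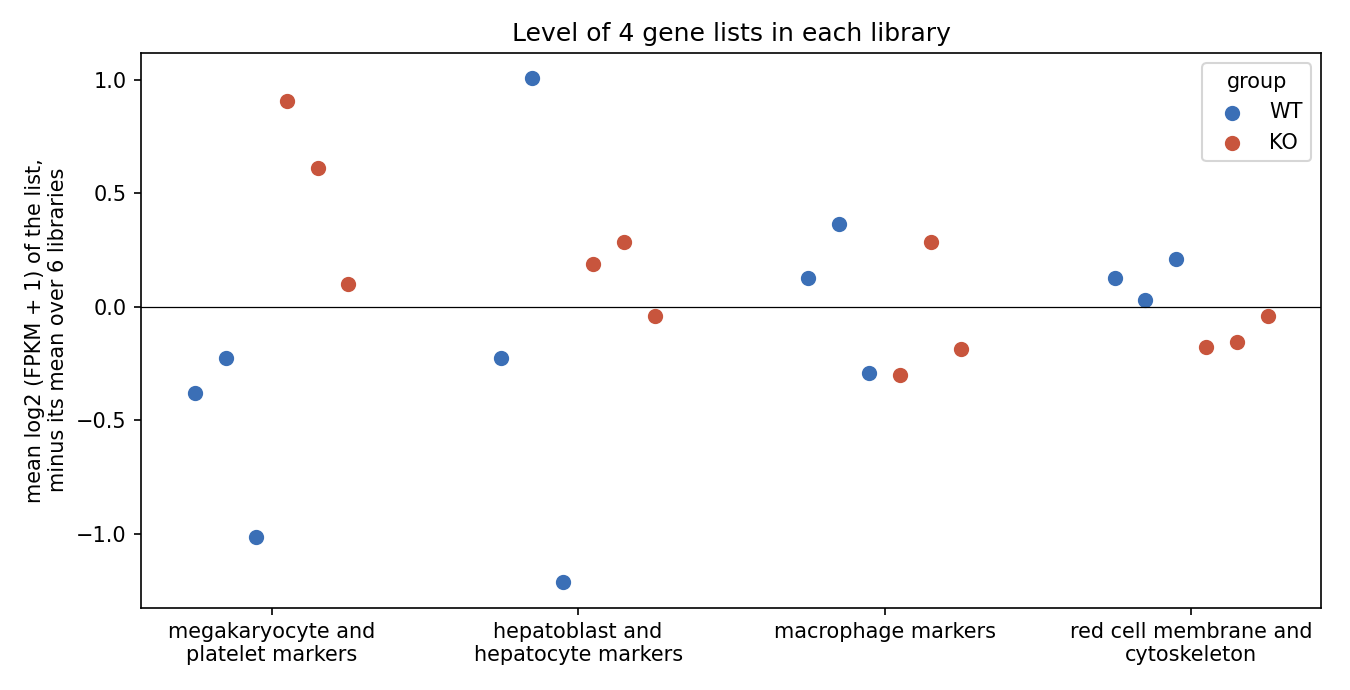
Mean log2 (FPKM + 1) of 4 gene lists in each library, as a difference from the mean of the list over 6 libraries (vertical axis), with blue points for WT and red for KO. Hepatoblast and hepatocyte markers spanned 2.22 log2 units among WT libraries and 0.325 among KO libraries.

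Of 25 genes of G2 and M phase 5 fell, 7 adjusted over the list alone: Ube2c from 242.2 ± 28.5 to 149.9 ± 2.68 FPKM, Nusap1, Cenpf, Ccnb2 and Mki67, the proliferation marker, which had a log2 fold change of -0.35. Of 26 genes of S phase and DNA replication 1 fell, also adjusted over the list alone, Ccne1, cyclin E1, with a log2 fold change of -0.65. With a library left out, calls of Nusap1 and Cenpf were kept in 3 of 6 fits, that of Mki67 in 1 and that of Ccne1 in 4. All 4 were lost with TPM and non-globin scaling, and the first 3 with no filter (adjusted p up to 0.1977, 0.2678, 0.313 and 0.1006 in the alternatives). Camera called both lower (adjusted p = 2.375e-11 and 1.646e-05), with adjusted p = 0.64 for each with an estimated correlation, and the S phase median of -0.09 became 0.03 with TPM scaling.

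Of 45 large-subunit ribosomal protein genes 4 rose, Rpl14, Rpl32, Rpl12 and Rpl5, and 44 had positive log2 fold changes, with a median of 0.17. Of 32 small-subunit genes 1 rose, Rps28, and all 32 were positive, with a median of 0.16. Adjusted over the list alone 11 rose in each. With a library left out, calls of Rpl32, Rpl12 and Rps28 were kept in 0 of 6 fits, that of Rpl5 in 1 and that of Rpl14 in 3, and all 5 calls were lost with each other scaling and with no filter (adjusted p up to 0.4243). Both lists were higher by camera (adjusted p = 2.69e-06 and 5.313e-05), with adjusted p = 0.64 for each with an estimated correlation, and with median-of-ratios scaling the medians were 0.07 and 0.06.

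Of 17 p53 targets 4 rose, also adjusted over the list alone: Sesn1, Sesn2, Cdkn1a and Bbc3, a gene that promotes apoptosis, with a log2 fold change of 0.57. Of 19 apoptosis regulators 1 rose and 1 fell, Bcl2l1, the survival factor BCL-XL, with a log2 fold change of -0.39. Of 21 genes of the integrated stress and unfolded protein responses Trib3 and Sesn2 rose and Eif2ak1, the haem-regulated kinase, and Ppp1r15a fell. Adjusted over the list alone these last 2 lists had 1 and 4 higher genes and 1 and 2 lower ones. With a library left out, the call of Sesn2 was kept in 4 of 6 fits, those of Sesn1, Bcl2l1, Trib3 and Eif2ak1 in 2, and those of Bbc3, Cdkn1a and Ppp1r15a in 1. With no filter all but that of Sesn2 were lost. Calls of Bcl2l1, Eif2ak1 and Ppp1r15a were lost with TPM and non-globin scaling (adjusted p up to 0.1518, 0.2734 and 0.1989 in the alternatives), those of Sesn1 and Cdkn1a with median-of-ratios and non-globin scaling, that of Trib3 with median-of-ratios scaling and a pseudocount of 0.1, and that of Sesn2 with non-globin scaling. Camera did not call these 3 lists (adjusted p = 0.21, 0.6513 and 0.3527), while fry, which asks whether members move one way on balance, gave adjusted p = 0.03603, 0.0484 and 0.03603, all towards higher values. Fry does not compare a list with other genes, and the medians of these lists, 0.15, 0.10 and 0.18, lay 0.05, 0.01 and 0.09 above that of all tested genes. With median-of-ratios scaling they were 0.07, 0.01 and 0.08. With no filter camera called the stress response list higher (adjusted p = 0.0218). Of 21 hypoxia and glycolysis genes 4 rose, 10 adjusted over the list alone, among them P4ha1 and Pklr, the red cell pyruvate kinase, from 203.4 ± 26.3 to 298.4 ± 3.87 FPKM, and Slc2a1, a glucose transporter, had -0.68. Calls of P4ha1 and Pklr were kept in 3 of the 6 fits and that of Slc2a1 in 5, and that of Pklr was lost with no filter and with non-globin scaling (adjusted p up to 0.1011). That list was higher by camera (adjusted p = 0.01297, and adjusted p = 0.66 with an estimated correlation), and had adjusted p = 0.05463 with a mean FPKM of at least 5 and 0.05488 without WT replicate 2 (range over the alternatives 0.0005613 to 0.05488).

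Of 15 genes of the erythropoietin and STAT5 response 5 rose, among them Podxl, Socs3 and Pim1, and 2 fell, Tfrc and Bcl2l1. Of 21 antioxidant genes 4 rose, among them Srxn1 and Gss, and 2 fell, Cat, the catalase gene, and Gclc. Of 18 immediate early and heat shock genes 4 rose, Junb, Klf6, Egr1 and Zfp36, and Dnajb1 fell. The call of Egr1 was lost in all 6 fits that left out a library, that of Gss was kept in 1, those of Klf6, Pim1 and Bcl2l1 in 2, that of Dnajb1 in 3, those of Tfrc and Gclc in 4, and those of Socs3, Srxn1 and Cat in 5. Calls of Junb and Podxl were kept in all 6. Calls of Egr1, Klf6, Gss and Pim1 were also lost with no filter and with median-of-ratios and non-globin scaling (adjusted p up to 0.1496, 0.1258, 0.2058 and 0.1364 in the alternatives), those of Dnajb1, Cat and Gclc with TPM and non-globin scaling (adjusted p up to 0.2164, 0.1383 and 0.1557), and that of Srxn1 with non-globin scaling (adjusted p = 0.09609). None of 11 interferon response genes and none of 11 mitochondrially encoded genes passed. Adjusted over the list alone, the first 3 of these lists had 7, 4 and 9 higher genes and 2, 2 and 1 lower ones. None of the 5 lists passed camera (adjusted p = 0.4928, 0.2768, 0.09599, 0.4928 and 0.6814). The immediate early and heat shock list was higher without WT replicate 3 (adjusted p = 0.001558) or KO replicate 2 (adjusted p = 0.03789), and with no filter, median-of-ratios, TPM or non-globin scaling (adjusted p = 0.01849, 0.02909, 0.02408 and 0.01465). The interferon list was higher without WT replicate 3 (adjusted p = 0.03962), and the mitochondrial list was lower without KO replicate 2 (adjusted p = 0.01747).

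Gene Ontology terms were tested in the same way. Of 2831 terms 26 passed camera, 9 higher and 17 lower. Mitotic sister chromatid segregation and structural constituent of chromatin, both lower, had the smallest adjusted p (camera, 0.0003173 and 0.0003759). Further lower terms were of the kinetochore, centromere and centriole, and higher ones of the ribosome and cytoplasmic translation. Terms of blood lineages among the 26 were megakaryocyte development (8 of 23 genes higher), heme biosynthetic process (3 of 21 lower) and erythrocyte development (8 of 35 lower). Integrin-mediated signaling also passed (12 of 53 higher). None passed with an estimated correlation (camera, smallest adjusted p = 0.9991), where 10 had an unadjusted p under 0.05. The number of terms was 7 without KO replicate 2, 13 without WT replicate 3, 17 without KO replicate 1, 53 without WT replicate 1 and 56 without KO replicate 3. At least 26 terms passed in 9 of the 10 splits of the 6 libraries into 3 and 3, the real split included.

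Of 85 genes past the threshold that the naming rule took apart from Gata1, 22 kept their call without each of the 6 libraries in turn, among them Apol11b, Cd82, Cd36, Hspa12b, Car1, Cldn13, Lyl1, Isg20 and Ube2c. The call was lost for 60 without KO replicate 2, 53 without KO replicate 1, 40 without WT replicate 3, 32 without KO replicate 3, 23 without WT replicate 1 and 15 without WT replicate 2. Calls of genes that the rule did not take, such as Klf1, Gp9 and Ccnb2, were not followed over the alternatives. WT replicate 1 stood apart in short structured RNAs, with 250.6 FPKM of Rn7sk against 0.745 to 3.09 in the other libraries.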

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

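The alternatives with protein-coding genes alone and with voom on the recovered fragments were chosen after the data were examined, as were the tests of other splits. The fall of Gata1 kept its direction and its side of the threshold under all 17 alternatives. Genes higher and lower in KO numbered 661 and 403, and 267 and 246 with no filter, where more genes were tested. Median-of-ratios scaling gave 251 higher, TPM scaling 137 lower, and non-globin scaling 240 higher and 125 lower. TPM and non-globin factors set WT replicate 1 apart, at 1.163 and 1.153 against 0.948 to 1.002 elsewhere. The summed FPKM of WT replicate 1 was 491620 against 400545 to 421672, and the short RNA Gm23935 made up 66609 of it. Scaling without this RNA was not run, and the cause of the median-of-ratios counts was not tested. TPM and non-globin scaling also let more genes past the filter, 13376 and 14186. A minimum absolute log2 fold change of 1 left 58 and 42. Leaving out 1 library gave 62 to 736 genes higher and 111 to 395 lower, with fewer samples. Gene Ontology terms numbered 26, and 9 with TPM scaling, 14 with non-globin scaling and 7 to 56 with 1 library left out. Camera with an estimated correlation called 0 lists higher, 0 lower and 0 terms, with 0 lists and 10 terms at an unadjusted p under 0.05; fry called 3 lists higher and 0 lower. Values of named genes stayed on their side of the threshold in 2016 cases, were lost in 382, gained in 48 and moved in 14, and 0 reversed. Depth limits low genes such as Gm22615, with 1 to 4 fragments per KO library.

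The labels do not say that same-numbered libraries are paired. Deviations from the group means of same-numbered libraries correlated at -0.097, 0.012 and 0.256, and not every library correlated best with its own number. So few libraries cannot show or exclude a pairing. With the replicate block 686 genes were higher and 386 lower, of which 457 and 334 were also called without it, with 7 lists higher, 10 lower and 54 terms. The block ended the calls of Cdkn1a, Hbb-bs, Ftl1, Egr1, Gss, Sesn1, Ppp1r15a, Gm11084, Rpl32, Rpl12, Rpl5 and Rps28, among others. The list added was that of immediate early and heat shock genes (adjusted p = 0.02725).

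Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 1064, and the highest other gave 2. For gene lists 2 gave as many, with 16 in the real split and 18 at most in another. For terms 9 gave as many, with 26 in the real split and 420 at most in another, a split of WT replicate 1, KO replicate 1 and KO replicate 2 from the rest. The splits are too few for a share under 0.05.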

Other observations

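All tests of explanations in this part were chosen after the results were seen. The genes named in this paragraph stand outside the lists and were chosen after their values were seen. Odc1, the first enzyme of polyamine synthesis, went from 482.4 to 250.1 FPKM, a log2 fold change of -0.95, and Smox, which oxidises spermine, had -0.75. Of the 10 genes of the term polyamine metabolic process 2 were lower, and the term was called by camera (adjusted p = 0.04474), with adjusted p = 0.9991 with an estimated correlation. The amino acid transporter gene Slc38a5 had -1.64, the lactate transporter gene Slc16a1 -0.92 and the bicarbonate transporter gene Slc4a5 -1.66. Lgals1, which encodes galectin 1, rose from 439.6 to 981.0 FPKM, a log2 fold change of 1.15.

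WT replicate 1 differed from the other libraries in abundant short RNAs. Gm23935 stood at 66609 FPKM there and at 2082 to 6199 elsewhere, and Rpph1 at 153.9 against at most 4.52. The mean of 41 histone genes was 0.40 log2 units lower in KO with this library and 0.09 higher without it. The pseudogene Gm8730 had 817.8, 863.7 and 897.9 FPKM in WT replicate 1, KO replicate 2 and KO replicate 3, and 28.3 to 30.8 in the other libraries.

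Of 21 megakaryocyte and platelet markers 14 were higher in KO, with a median log2 fold change of 1.18 and adjusted p = 0.64 for the list with an estimated correlation. The lowest median with 1 library left out was 0.967, without WT replicate 3, which argues against a single library as the whole cause. The lowest median over the other scalings was 1.10, which argues against scaling. A larger share of megakaryocyte-lineage RNA in KO is a candidate explanation. Markers moved together between libraries of 1 group (the median correlation between pairs of markers was 0.962 over their deviations from the group means). This correlation does not test the difference between the groups. All 21 log2 fold changes were positive, but Ppbp, chosen after its values were seen, had 51.0 to 113.9 FPKM in WT libraries and 57.4 to 102.0 in KO. Higher transcription of the same genes in other cells was not tested.

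More genes were higher than lower in KO. The lower globin share of fragments in KO would shift all other genes by 0.0327 on the log2 scale, less than the observed median of 0.09, which argues against it as the whole cause. The share of higher genes among those changed was 62.1% as deposited, 33.65% with median-of-ratios scaling, 82.1% with TPM scaling and 65.8% with non-globin scaling. In the last 2 scalings the factor of WT replicate 1 stood apart, at 1.163 and 1.153 against at most 1.002 elsewhere. Median-of-ratios scaling brings the median of all genes to 0.01, which removes an overall excess whether or not it is real. Its lower share therefore does not decide between the sources, and scaling stays open.

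Of 24 red cell membrane and cytoskeleton genes 12 were lower in KO, 1 was higher and 11 did not pass. The median log2 fold change was -0.25, and the list had adjusted p = 0.64 with an estimated correlation. The median nearest to 0 with 1 library left out was -0.221, without WT replicate 3, which argues against a single library as the cause. The median was -0.35 with median-of-ratios, -0.20 with non-globin and -0.12 with TPM scaling, so its size depends on the scaling. Non-globin and TPM scaling lower the values of WT replicate 1 by outlying factors of 1.153 and 1.163. The megakaryocyte minus macrophage level of the lowest KO library lay 0.793 log2 units above that of the highest WT library, more than the larger SD within a group, 0.521. Both lists were chosen after their values were seen, and the megakaryocyte list had the highest median of all lists. A gap was therefore likely from the choice alone and does not test whether cell types changed alike. The measure also holds no erythroid gene and cannot decide on a smaller share of erythroid cells. Hepatoblast, stellate, neutrophil, endothelial and lymphoid medians were 0.29, 0.33, 0.25, 0.18 and 0.03. Macrophage and mast cell medians were -0.135 and -0.168, so a smaller erythroid share stays open. A rise of megakaryocyte-lineage cells alone stays open, and so does the lower Gata1 level, which the design names and which was not tested apart from the genotype.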
